A study of Halobacterium salinarum NRC-1 with 36 samples.

How the data were processed

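The samples were 18 time points of Halobacterium salinarum NRC-1 in darkness, each on 2 arrays against a mid-log reference, with the sample in Alexa 532 on one and in Alexa 647 on the other, per the labels. This technical dye exchange is 1 RNA pair, so the 2 arrays were averaged and counted as 1 replicate. No 2 arrays held identical values. The replicate number stands for the dye orientation only, and principal component 1 of the turned arrays, with 46.9% of the variance, separated the orientations except that the 1260 min Alexa 532 array lay at -1.5, the score of the 300 min Alexa 647 array.

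The deposited scanner files give spot and background intensity on a linear scale for 10752 spots in 48 print blocks, in a high-gain and a low-gain scan of each dye, per the file headers, and were not normalized. The value table that the authors deposited holds log10 ratios of Alexa 532 over Alexa 647, as found by setting each column against that array's scanner values. Correlations with the log ratio of spot means were 0.886 to 0.995 and slopes 0.8 to 1.03, once spots were matched row by row over the array. The table was not turned for the dye exchange, and its column medians lay between 0.036 and 0.211. How the authors normalized it, and how its 557 to 831 empty cells per array were chosen, is not given in the sources used here. Empty cells were identical within 4 blocks of arrays, called A to D. Block A held the Alexa 532 arrays up to 1740 min, B those from 1980 min, C the Alexa 647 arrays up to 2940 min and D those from 3180 min.

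Spot means of the high-gain scans were background corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and normalized by loess within print blocks, without scaling between arrays. The plan named this background correction and loess, without saying over what. Before any comparison was fitted, combinations of spot measure, scan, background and normalization were compared on the agreement of spots, array parts and dye exchange, and loess within print blocks was picked from them. In a later table of 36 combinations the one used ranked 2 on dye-exchange agreement among probes at or above the median brightness (median r 0.57) and 13 over all probes (0.04, where the highest was 0.48). The same loess without background correction stood higher on both (0.58 and 0.32). The comparisons were fitted first with loess within print blocks. Loess over the whole array was then made the main setting for a time, as the more literal reading of the plan. After its calls had been seen, loess within print blocks was put back, on the ground of the dye-exchange agreement (0.57 against 0.36). The choice was therefore not blind to the results, and both counts are given in the report.

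Ratios were turned to sample over reference and the 4 spots of a probe averaged. The 4-spot layout holds for all 133 named genes and was applied to the 2555 unnamed probes, some of which may be controls. Each named probe had 1 symbol, 0 had several, and 0 gene IDs matched the reference table, which is of another strain, so that symbols are those of the array annotation. After turning, the dye orientations of a time point correlated at r between 0.36 and 0.69 among brighter probes and between -0.51 and 0.33 among dimmer ones. Values of dim probes therefore carry dye effects, and may carry background effects, which were not measured apart. The lowest r among brighter and among dimmer probes, 0.36 and -0.51, were both at 3900 min, in the third 24 h. Arrays of 1 orientation correlated at 0.14 or above. Spots with a median above background made up 42.7% to 88.1% in Alexa 532 and 70.7% to 91.3% in Alexa 647, and the number of arrays limits the precision.

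Tests used lmFit and eBayes on the 18 log2 values with Benjamini-Hochberg adjustment at 0.05. The third against the first 24 h was fitted with span and 24-h cosine and sine, the rhythm as an F-test on cosine and sine beside linear and quadratic time, and the 12-h comparison with linear and quadratic time. Gene lists of at least 3 named members were tested with camera (preset, then estimated correlation) and fry, and 10 lists had no named member. These were the lists for gas vesicles, DMSO and TMAO respiration, ATP synthase, RNA polymerase, general transcription factors, KaiC and Cir, the archaellum, iron, potassium and transposases. The lists for the respiratory chain, oxidative stress, ribosomal proteins, arginine and phosphate had 1 or 2 named members and were not tested as sets. For these, nuoL gave -0.18 and sdhC 0.03, msrA -0.16 and dpsA 0.01 between the third and the first 24 h, none called.

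Named genes were set by rule beforehand: up to 6 largest and 6 smallest called differences with the same sign in both orientations, up to 12 called amplitudes with peaks within 4 h, and up to 3 called members per list. The rule also took bop, brp, bat, crtB1, hop, arcA, arcB, arcC, dmsA, gvpA, phr1, phr2, sod1, sod2, perA and the KaiC and Cir genes always, of which bat, hop, arcA and arcC are named in the annotation. Where fewer than 4 passed, the 6 smallest p were to be named. For 60 against 0 min it took the 6 largest and smallest changes of at least 1 log2. Most probes so picked are unnamed, so at most 2 per direction are printed. Other genes were named after their values were seen, as members of the lists or of the named set.

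The fits were tested on simulated data with the spread of these probes, 2688 probes and 50 per size. All sizes were simulated together for each comparison, with Gaussian noise independent over time. For the third against the first 24 h, 58% of probes with a difference of 0.5 and 94% with 1 were recovered. For the 12-h comparison 80% were recovered at 0.5. Of 2488 unchanged probes in these data, 6, 14 and 14 were called for the third against the first 24 h, the rhythm and the 12-h comparison. With no effect in any probe, 0 calls were made in each. Alternatives covered background, normalization, brightness, dye orientation, time points, variance model, trend and period. Those for loess over the whole array, spot median, low-gain scans, brighter probes, array blocks, arrays that stand apart, gene lists without 0 min and 10 further periods were chosen after seeing the data. Of the alternatives planned for each comparison, 1 was run and is not reported here. It moved the count for the third against the first 24 h by over 1.5 times, left the counts of 0 as they were, and is in no tally or range of alternatives given here. The fits took time points as independent. Plots were made with matplotlib 3.10.9.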

Results

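Halobacterium salinarum NRC-1, a salt-loving archaeon that makes ATP with the light-driven proton pump bacteriorhodopsin, was grown with air at 42 °C. Cultures were entrained for 72 h to cycles of 12 h light and 12 h dark at 150 µE, and RNA was then taken in the dark at 18 time points from 0 to 3900 min. After 0, 60 and 300 min the samples followed every 4 h. Each RNA was hybridised against a standard mid-log reference on 2 arrays with exchanged dyes, which were averaged and counted as 1 replicate. The arrays gave 2688 probes of 4 spots each, of which 133 carried a gene symbol in the annotation used here and 2555 did not. The first 24 h held 7 time points, the second 6 and the third 5. The labels do not say whether time points came from separate cultures, so that p-values measure only the spread between these samples, which may be technical. In fits of single arrays over all probes, the 2 arrays of a time point had a residual correlation of 0.02 to 0.03. Little of that spread was thus shared by the 2 arrays of 1 RNA.

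The first comparison asked what changed between the first and the third 24 h of darkness. Differences are from the fit, which also holds a 24-h cosine and sine. The mRNA of infB, a translation initiation factor, was 1.45-fold higher in the third 24 h (log2 difference 0.54 ± 0.1 SE, adjusted p = 0.00975). Its level against the reference was -0.58 ± 0.14 (SD, n = 7 time points) early and -0.08 ± 0.3 (SD, n = 5) late. The ribosomal protein gene rpmC was 1.34-fold higher (0.42 ± 0.08, adjusted p = 0.00926). Its level went from -0.43 ± 0.14 to -0.04 ± 0.08. The dihydropteroate synthase gene folP, of folate synthesis, differed by 0.52 ± 0.12 (adjusted p = 0.0313). Enolase, encoded by eno, a step of glycolysis and gluconeogenesis, differed by 0.38 ± 0.09 (adjusted p = 0.0325). The gene glmS, for the enzyme that makes glucosamine 6-phosphate, differed by 0.41 ± 0.1 (adjusted p = 0.0342).

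Over all 2688 probes, limma called 85 past an adjusted p of 0.05, 66 higher and 19 lower in the third 24 h. The size of the called differences ranged from 0.25 to 1.07 log2, with a median of 0.43. These 5 genes were the named ones among the calls, and all rose. An unadjusted p under 0.05 was met by 565 probes, where 134.4 would be expected by chance. Among unnamed probes, the one that starts at spot 3211 rose most (0.95 ± 0.18) and the one at spot 577 fell most (-1.07 ± 0.17), followed by spots 11 (0.79 ± 0.15) and 1335 (-1.05 ± 0.17). Each of these 4 probes lay below the median brightness, as did 29.4% of the 85 calls. The calls were crowded on the array: 28 of the 85 lay in the first of 6 rows of print blocks, where 14.2 would be expected from its share of probes, among them infB, folP, glmS and the probes at spots 11 and 577. Among the 6 largest falls, those at spots 577, 587, 649, 711 and 655 lay close together in 1 print block of this row. The same print block held infB, folP and spot 11, so a local fault of the array cannot be told from a change in mRNA there.

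Adjusted over the 133 named genes alone, 11 passed, 8 higher and 3 lower. Besides the 5 genes above these were purF, the first committed step of purine synthesis (0.47 ± 0.13), phoU, a regulator of phosphate uptake (0.46 ± 0.13), and rpl12p, a protein of the ribosomal stalk (0.48 ± 0.13), each with an adjusted p of 0.0331. The phoU difference was 0.77 on the Alexa 532 arrays and 0.15 on the Alexa 647 arrays, and it turned to -0.21 with array blocks as a term, as that of purF turned to -0.09 in the authors' value table. The lower ones were glpK, glycerol kinase (-0.39 ± 0.12), bat, the activator of bacteriorhodopsin synthesis (-0.37 ± 0.11), and thiC, of thiamine synthesis (-0.28 ± 0.08), with an adjusted p of 0.0447. The glpK difference was -0.72 on the Alexa 532 arrays and -0.07 on the Alexa 647 arrays, and 0 from the low-gain scans. Over all probes the adjusted p of these 6 genes lay between 0.053 and 0.0755.

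**Figure D1:**
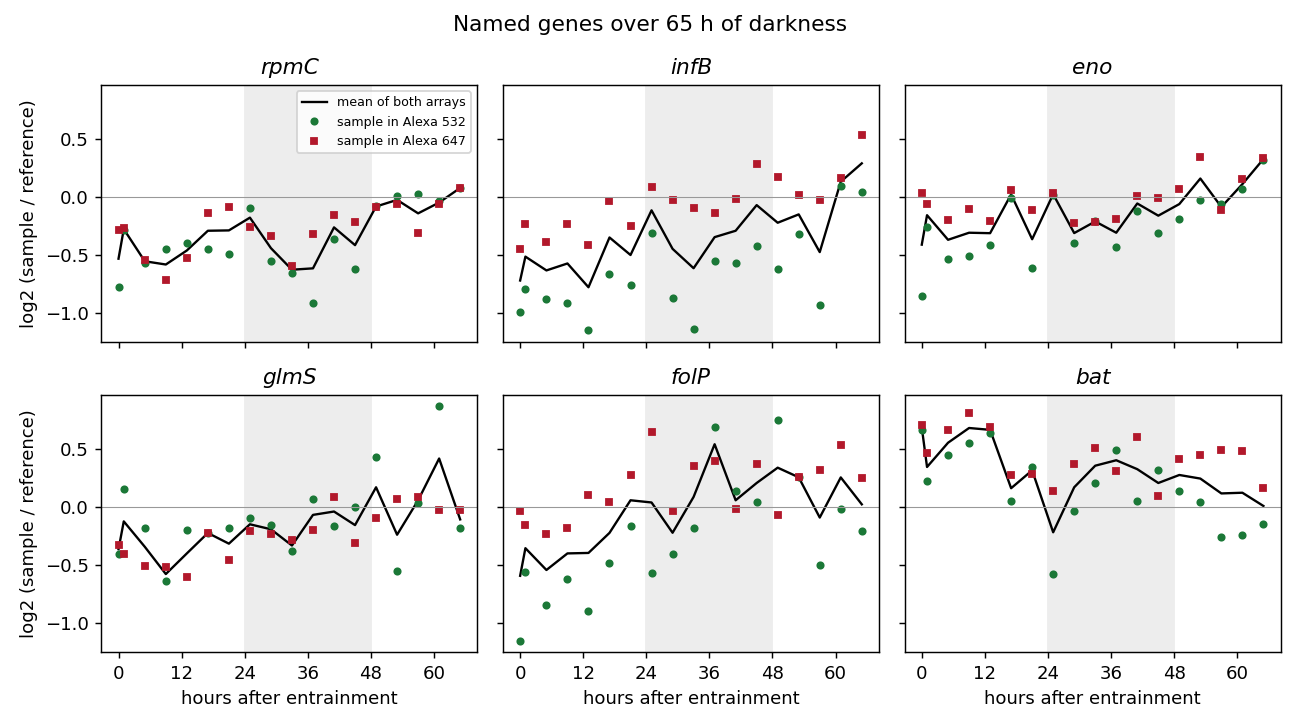
Log2 ratio of sample to reference (vertical axis) of 6 genes against hours after entrainment (horizontal axis). Circles and squares are the arrays with the sample in Alexa 532 and in Alexa 647, the line is their mean and the grey band marks the second 24 h, and the means of rpmC went from -0.43 in the first 24 h to -0.04 in the third, and those of bat from 0.48 to 0.15.

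Of the 25 gene lists set before the data were examined, 15 had a named member and 10 had at least 3. The list of bacteriorhodopsin and retinal pigment genes had 4 named members, all with lower values late: bat, sop1 (-0.19 ± 0.09), hop, the light-driven chloride pump (-0.13 ± 0.08), and sop2 (-0.12 ± 0.07). The bacteriorhodopsin gene itself, bop, was not named in the annotation, nor were brp and crtB1, so the list does not cover them. Neither of the sensory rhodopsins sop1 and sop2, nor any other member, passed over all probes, and 1 of the 4 passed adjusted over the list alone. As a set they fell by camera with a preset correlation (adjusted p = 0.0461) but did not pass with an estimated correlation (adjusted p = 0.218). Fry, which tests whether the members move on balance one way and does not compare them with other genes, gave an adjusted p of 0.00526. Over the other scalings camera's adjusted p ranged from 0.0262 to 0.261, without the 0 min time point it was 0.106, and without the Alexa 532 array of 0 min alone it was 0.0413. With loess over the whole array, 1 of the 4, hop, had the opposite sign (0.04).

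The 5 genes of the TCA cycle passed as a set by the same test (adjusted p = 0.0461), which did not hold with an estimated correlation (adjusted p = 0.448). Their mean difference was 0.24, and without the 0 min time point, whose arrays stand somewhat apart, it was 0.17 and the set did not pass (camera adjusted p = 0.125, and 0.113 without its Alexa 532 array alone). There icd gave 0.02, mdh 0.11 and citZ 0.18. The largest were sucC (0.43 ± 0.14) and sucD (0.29 ± 0.14), the subunits of succinyl-CoA synthetase, and citrate synthase, citZ, gave 0.22 ± 0.1. None passed over all probes, and sucC passed adjusted over the list alone. Fry gave an adjusted p of 0.0996. Over the other scalings camera's adjusted p ranged from 0.0241 to 0.626, and 4 of the 5 were positive in the authors' value table. The 3 genes of glycolysis and gluconeogenesis gave a mean of 0.18 (camera adjusted p = 0.187), of which eno was called and ppsA (0.13 ± 0.09) and tpiA (0.03 ± 0.09) were not.

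No other list passed camera (adjusted p of 0.417 or more) or fry. The smallest fry adjusted p, 0.0574, was that of the translation factor and synthetase list and of the DNA repair list. Fry's mixed test asks whether members differ in either direction. Its unadjusted p was 0.00195 for the translation factor and synthetase list and 0.00528 for the purine and pyrimidine list. Of 13 genes that the pattern for translation factors and aminoacyl-tRNA synthetases took up, 1 was called, and this was glmS, which is not a translation gene. The patterns did not take up infB and rpmC, both called over all probes, so that the lists for translation factors and for ribosomal proteins lack them. The largest synthetase value was that of lysS (0.29 ± 0.11, adjusted p = 0.144). The 11 purine and pyrimidine genes had values from -0.28 to 0.47 with none called over all probes and 2, purF and purD, called adjusted over the list alone. The 11 chemotaxis and transducer genes ranged from -0.2 to 0.11 with none called. Of 4 DNA repair genes none was called over all probes, and mutL (-0.31 ± 0.13) and uvrB (-0.24 ± 0.09) passed adjusted over the list alone, though mutL gave -0.76 on the Alexa 532 arrays and 0.13 on the Alexa 647 arrays. Of 6 genes in the chaperone and proteasome list none was called over all probes, and 1, panB (0.59 ± 0.19), passed adjusted over the list alone. It belongs to pantothenate synthesis and was caught by the pattern for the proteasome gene pan1 (0.1 ± 0.09). The 4 replication genes, among them gyrA (-0.07 ± 0.1) and gyrB (0.23 ± 0.15), and the 4 cobalamin genes had no call. Of the arginine fermentation genes, arcA gave -0.27 ± 0.1 (adjusted p = 0.141) and arcC 0 ± 0.09, and arcA passed adjusted over the list alone. So did rpl12p and phoU, each the 1 gene its list took up.

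**Figure D2:**
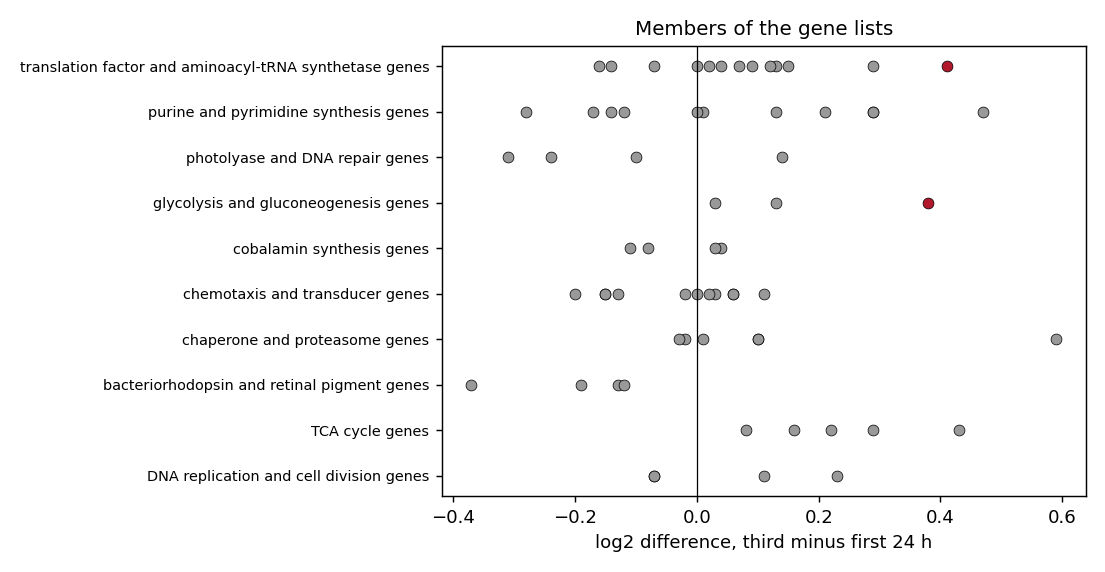
Log2 difference between the third and the first 24 h (horizontal axis) for each member of the 10 lists with at least 3 named genes (vertical axis), each point 1 gene, red where limma called it over all probes. The 4 named genes of the bacteriorhodopsin and retinal pigment list, bop not among them, lie below 0, though hop was at 0.04 with loess over the whole array. The 5 TCA cycle genes lie above 0, though 4 of 5 did in the authors' value table.

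The calls depended on the normalization, on the arrays and on the time points, with 19 to 111 calls when 1 time point was left out. Loess over the whole array, in place of loess within print blocks, called 186 probes, and both counts were known when the latter was settled on. The arrays fall into 4 blocks that nearly follow time, and only block C, with 14 arrays, held time points of both spans, 1 of its arrays being of the third 24 h. With block as a term 40 probes were called. This fit used single arrays in place of the averaged time points and took the 2 arrays of a time point as correlated. The correlation was estimated at 0.03, so the 2 arrays of 1 RNA counted almost as separate replicates. The adjusted p-values of the block fit may therefore be too small. In the block fit infB (0.65, adjusted p = 0.0234) and rpmC (0.61, adjusted p = 0.0205) passed, while eno (0.35, adjusted p = 0.17), glmS (0.44, adjusted p = 0.186) and folP (0.09, adjusted p = 0.87) did not. In the authors' value table infB gave 0.07 (adjusted p = 0.358) and eno 0.18 (adjusted p = 0.246). Over the alternatives reported the adjusted p ranged from 0.000549 to 0.0807 for rpmC, from 0.00217 to 0.358 for infB, from 0.0029 to 0.246 for eno, from 0.00118 to 0.337 for glmS and from 9.97e-06 to 0.87 for folP. All 85 called probes had the same sign in both dye orientations, which is likely for probes picked on the mean of both. Fitted alone, the orientations called 14 probes (Alexa 532, 0 of them named) and 334 probes (Alexa 647), with 0 in both. Unrelated calls would also share few probes at these counts, so the 0 shows neither agreement nor conflict. Across probes, which are not independent replicates, their differences correlated at r = -0.11, at 0.42 among probes at or above the median brightness and at -0.29 among the rest. Dye-exchange agreement itself was mostly lower in the third 24 h. Over all probes the 2 orientations of a time point correlated there at -0.25, -0.3, -0.18, 0.08 and -0.34. At the earlier time points r lay between -0.05 and 0.44.

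The second comparison asked whether any mRNA kept a 24-h rhythm in the dark, as sampling every 4 h after entrainment implies. Among named genes, the largest fitted amplitudes were those of deoC (0.23 log2), nadA (0.22) and gatC (0.19), all dim probes, at brightness percentiles 12.2, 11.9 and 1.9. The amplitude was 0.43 on the Alexa 532 arrays and 0.12 on the Alexa 647 arrays for deoC, and 0.1 and 0.34 for nadA. The retinal pigment genes had small ones, with 0.12 for bat, 0.03 for hop, 0.02 for sop1 and 0.03 for sop2. Amplitudes were 0.09 for arcA and 0.02 for arcC. The smallest unadjusted p of a named gene was 0.0648, for infB. No probe of the 2688 passed limma's F-test on the 24-h cosine and sine (smallest adjusted p = 0.994). An unadjusted p under 0.05 was met by 115 probes, where 134.4 would be expected by chance. The 6 probes with the smallest p were unnamed. No member of the KaiC and Cir family, homologs of the cyanobacterial clock protein, was named here. In simulated data with the spread of these 2688 probes, 96% of 50 probes with an amplitude of 0.5 and 50% of those with 0.25 were recovered. These data held rhythmic probes of all sizes at once, beside 2488 unchanged ones, with noise independent over time. If only a few probes were rhythmic, the adjusted threshold would be stricter and a smaller share would be recovered.

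The third comparison set the first 12 h of each 24 h (10 time points) against the second (8 time points). The labels do not say which of them followed lights on. The difference was -0.05 for bat (95% interval -0.25 to 0.16), 0.01 for hop (-0.12 to 0.14), -0.13 for arcA (-0.3 to 0.05) and -0.03 for arcC (-0.17 to 0.11). The smallest unadjusted p among named genes was 0.0205, for deoC, the deoxyribose-phosphate aldolase gene (-0.39 ± 0.15, with -0.66 on the Alexa 532 arrays and -0.12 on the Alexa 647 arrays). The transducer gene htr4 (-0.13 ± 0.06) and the histidine gene hisA (0.15 ± 0.07) followed. No probe passed in limma (smallest adjusted p = 0.864), and 131 had an unadjusted p under 0.05 against 134.4 expected by chance. No gene list passed camera, and the smallest adjusted p was 0.442.

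**Figure D3:**
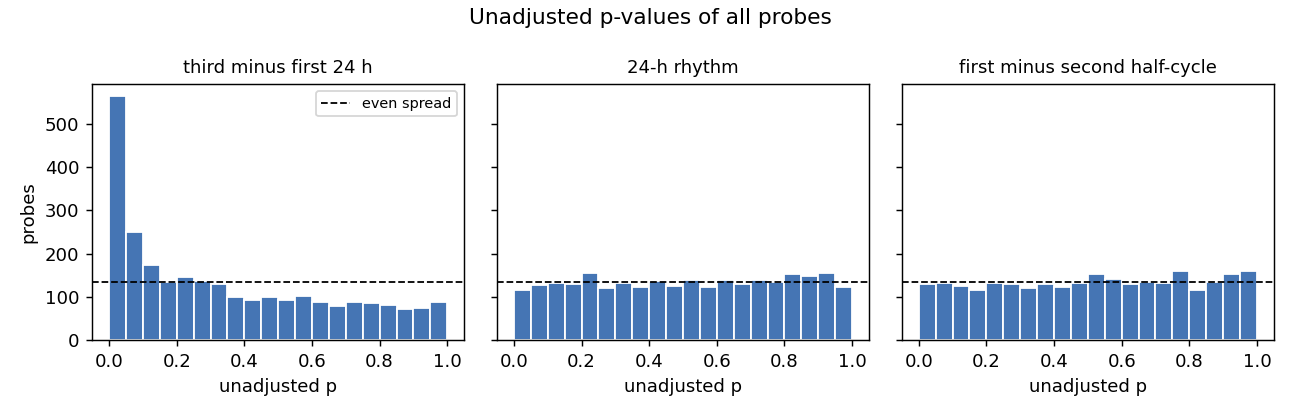
Number of probes (vertical axis) by unadjusted p (horizontal axis) for the 3 comparisons, with the even spread that chance gives as a dashed line. The count of probes with p under 0.05 was 565 for the third against the first 24 h, 115 for the 24-h rhythm and 131 for the 12-h comparison.

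The shortest interval, 0 to 60 min, had 1 RNA at each end and was not tested. The difference in bat was -0.34 (-0.44 and -0.24 on the 2 dye orientations), in arcA -0.34 (-0.06 and -0.63), in arcC -0.35 (-0.22 and -0.48) and in hop 0.23 (0.79 and -0.34). The named genes with the widest differences included panB (0.88), thiL (0.82) and sucD (0.81), and on the other side nadA (-0.88) and pyrI (-0.82). On the Alexa 532 and the Alexa 647 arrays panB gave 1.29 and 0.46, thiL 1.08 and 0.56, and sucD 1.48 and 0.14. Those of nadA were -1.25 and -0.52, and those of pyrI -0.76 and -0.89. A difference of at least 1 log2 with the same sign in both orientations was found in 53 probes, 15 higher and 38 lower at 60 min, none of them named. Over all probes the differences on the 2 orientations correlated at r = 0.07 (0.33 among those at or above the median brightness), and 28 of the 53 probes lay below the median brightness. Without background correction the count was 4, and in the authors' value table it was 1.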

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

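The tests of array position, of the normalization and of the 0 min array were chosen only after the results were seen. Of 42 groups of 5 to 7 time points, 1 held a value far from the others, where about 2.1 would be expected by chance. This was arcA, arginine deiminase, at 3420 min, with -0.69 against -0.27 for the nearest and -0.18 for the other end of the third 24 h (n = 5), and its 2 arrays read -1.27 and -0.12.

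The first pattern is the 85 probes called between the third and the first 24 h. Of 100 splits of these 12 time points 1, the real one, gave as many and the highest other gave 68. Chance can thus be excluded for time points that vary independently, but noise shared by neighbouring time points is not excluded. The real split nearly follows the array blocks, and with block as a term, in a fit of single arrays, 40 probes were called. Against the choice of loess as the whole cause stands that 63 of the 85 were also called with loess over the whole array. The shared count was 75 with equal scale between arrays, 72 with spot medians and 70 without background correction. It was 51 with median centring, 47 from the low-gain scans and 46 in the authors' value table, so normalization in a wider sense stays open. A fault in one part of the array stays open: the 2 parts alone called 34 and 4 probes with 2 in both and correlated at r = 0.49 over all probes, 28 of the 85 lay in the first row of print blocks against 14.2 expected, and the median ratio of the smaller to the larger difference, 0.72, was first read as excluding this but is over probes picked for a large mean of both parts. Array blocks stay open too: of the 14 probes called in the Alexa 532 arrays, 71.4% had slopes of the called direction within block C of the Alexa 647 arrays (exact 95% interval 41.9 to 91.6, against 52.8% of all probes) and 57.1% within block D (28.9 to 82.3), and of the 334 called in the Alexa 647 arrays 59.3% did within block A and 60.8% within block B, against 53.8% and 54.7% of all probes. Change with time in the dark or with the age of the culture stays open and untested.

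The second pattern is the absence of calls for the 24-h rhythm and the 12-h comparison. For the latter, other splits decide nothing, since 100 of 100 must give at least the real count of 0, and the highest other gave 1. For the rhythm, simulated amplitudes of 0.5 were recovered in 96% of cases, which met the bound set beforehand for ruling out that amplitudes were too small for the spread. That reading was withdrawn after the value was seen, because the bound was wrong: it rests on simulated settings, with many rhythmic probes at once, and on 1 size. Amplitudes of 0.25 were recovered in 50%. Rhythms too small for the spread may therefore be present, and no biological explanation was tested.

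The third pattern is the count of 53 probes in the first hour, against at most 47 in any other step. The Alexa 532 array of 0 min had the lowest mean correlation with the others of its orientation, 0.59 against 0.61 to 0.75, which met the criterion for an array that stands apart. This was first read as bearing that explanation out, and the reading was changed after the Alexa 647 array of 0 min was found to be the lowest of its own orientation too, at 0.63 against 0.64 or more. The 2 arrays carried the same RNA, yet on principal component 2 of the turned arrays they lay at 26.5 (Alexa 532) and -0.4 (Alexa 647). What set the Alexa 532 array apart there was thus not shared by its partner. The Alexa 647 array had the highest median backgrounds of all arrays, 9050 in Alexa 532 and 11762 in Alexa 647. Whether the RNA at 0 min differed as well cannot be told, since 1 RNA was taken.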

How the results depend on the processing

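The alternatives for whole-array loess, spot median, low-gain scans, brighter probes, array blocks, arrays that stand apart and further periods were chosen after seeing the data. The count of 85 for the third against the first 24 h stayed within 1.5 times under 15 of the 35 alternatives reported, and the cause of the other changes was not tested. It was 187 without background correction, 147 with equal scale between arrays, 257 with median centring (156 higher, 101 lower), 186 with loess over the whole array (111 and 75), 207 from the low-gain scans, with plain background subtraction and a floor (106 and 101) and 809 from the authors' value table (456 and 353). It was 137 among probes at or above the median brightness, where fewer probes were tested, 55 without cosine and sine, and 41 without the Alexa 532 arrays of 0, 2220 and 3660 min. Fits of 36 arrays took the 2 arrays of a time point as correlated. With the dye orientation, that is the replicate number, and the array number series, which sets block D apart, as terms, the count was 144. With array blocks A to D as terms it was 40, of which 21 were among the 85. The replicate numbers pair no cultures. Leaving out 1 dye orientation gave 14 (Alexa 532 alone) and 334 (Alexa 647 alone). Leaving out 1 time point gave 19 to 111, with 29 without 300 min, 29 without 540 min, 31 without 780 min, 19 without 3180 min, 25 without 3420 min, 28 without 3660 min and 37 without 3900 min. Of the called named genes, rpmC passed under 33 of 35 alternatives, infB under 31, eno and glmS under 23 and folP under 22 of 34, each with a positive difference throughout. Many of these alternatives only left out 1 time point and kept the same normalized values, so the tallies say less about the processing. With the Alexa 532 arrays alone none of these genes passed. From the low-gain scans neither rpmC nor infB passed. With median centring and in the authors' value table infB did not pass, while rpmC did. The 24-h rhythm gave 0 under 48 of 49 alternatives, with 48 to 216 probes at an unadjusted p under 0.05. Clock time as a factor gave 1, an unnamed dim probe (adjusted p = 0.0465). The 12-h comparison gave 0 under all 36. The count of 53 for the first hour was 4 without background correction, 110 with median centring, 105 with loess over the whole array, 31 with spot medians and 1 from the authors' value table. Signal over background limits the dim probes.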

Other observations

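The tryptophan synthesis genes trpB and trpC, and gdhA1 and secY, were singled out only after their values were seen. In the first 24 h trpB stood at 1.03 ± 0.27 (SD, n = 7) above the mid-log reference on the log2 scale and trpC at 0.8 ± 0.23. In the second 24 h trpB was at 0.27 ± 0.28 (n = 6) and trpC at 0.57 ± 0.18, and in the third 24 h the levels were 0.66 ± 0.22 (n = 5) and 0.54 ± 0.14. The differences, -0.35 ± 0.15 and -0.26 ± 0.11 (SE), did not pass over all probes (adjusted p = 0.194 and 0.198). The trpB difference was -0.79 on the Alexa 532 arrays and 0.09 on the Alexa 647 arrays, and that of trpC -0.47 and -0.05. The glutamate dehydrogenase gene gdhA1 gave 0.5 ± 0.16 (adjusted p = 0.0808) and secY, of the protein export channel, 0.18 ± 0.06 (adjusted p = 0.0948).

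A hypothesis set before its test was that a weak 24-h component shared by many probes may be present although no single probe passed. Detrended profiles of the 1344 probes at or above the median brightness correlated at a mean of 0.04 between the 11 pairs of time points 24 h apart and at -0.09 between the 14 pairs 12 h apart. The difference, 0.13, had a one-sided p of 0.105 in a permutation test of the time order. Other lags were mixed. The mean was 0.1 at 48 h (5 pairs) but also 0.03 at 36 h (8 pairs), where a 24-h component would give a low value. The lowest mean was -0.16, at 20 h (12 pairs). Time points were permuted after detrending, so correlation left by the trend fit is not in the chance values. The hypothesis stays open. In the 36-array fits the arrays of 1 time point had a residual correlation of 0.02 to 0.03.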
